A study of Drosophila melanogaster with 3 samples.

How the data were processed

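Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole white prepupae of *Drosophila melanogaster*, males and females pooled, from a transgenic line that expressed the homeodomain protein OdsH (Odysseus) fused to GFP at its C terminus. Per the labels, the fusion protein was precipitated with an antibody to GFP, chromatin was sonicated, and fragments ranged from 200 to 800 bp. The labels give 1 group of 3 biological replicates, which are named by the number in each sample's description. No second stage, genotype or sex was sampled, so the comparisons made here are between replicates and between bound regions and the rest of the genome.

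The deposited peak lists cover genome builds dm6 and dm3. For each replicate and for the pool of the replicates the authors deposited 30000 rows described as peaks and background meant as input for the irreproducible discovery rate (IDR) procedure, and 1 optimal IDR set for the series. Per the deposited file lists that accompany each library, the 3 replicate lists were called against the same single control alignment per build, so shared features of that control enter all 3. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak was computed by the authors' peak caller and was used only to rank or describe peaks within 1 list. The deposited −log10 q-value is capped at 1 value for many peaks (90.0% of the IDR set), so it was not used to rank. The deposited summit offset gave each summit position. Reads and depth per library were not analysed here, so the sequencing depth behind each peak is unknown and no interval that needs it was computed.

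The IDR set on dm6 was the main peak set. All 8700 of its rows were the 8700 strongest rows of the pooled list, so taking the strongest pooled rows gave the same peaks and was no separate test. Coordinates are 1-based on dm6. Genes and transcription start sites (TSSs) came from the Ensembl release 115 annotation of the BDGP release 6 assembly, whose sequence matches dm6. Transposable elements were left out, which left 13945 protein-coding genes on the 6 arms (2L, 2R, 3L, 3R, 4 and X). No dm3 sequence or annotation was used here, so dm3 lists entered only counts, replicate support, signal correlation and arm shares, and no coordinate was converted between builds.

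An IDR peak was called supported by a replicate when at least 1 bp of it overlapped 1 of that replicate's 8700 strongest peaks. The same shares were computed for 100 random placements on the same arms. Spearman's rho of the authors' signal value was computed across IDR peaks, which are not independent replicates, so no p-value was attached. Arm shares were compared with assembled length by exact binomial tests with Clopper-Pearson intervals at 95%, which cover counting error only. The share of summits within 500 bp of a TSS was compared with 1000 random placements (one-sided permutation test). Medians of signal values were compared by permutation over peaks with 100000 resamples in the main test and 10000 in alternatives (two-sided). Each statistic was also computed on each replicate's own 8700 strongest peaks, and the mean ± SD over the 3 replicates is given as the replicate error.

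Motifs were 15 words fixed before the data were examined, 2 of them unrelated control words, searched on both strands in 101 bp windows centred on summits. Each share was compared with that in windows 500 bp to either side (Fisher's exact test, two-sided, Benjamini-Hochberg over the 15 words). Other backgrounds, chosen beforehand, were summit windows shuffled with dinucleotide counts kept and positions on the 6 arms, outside IDR peaks, matched on GC content and on lying within 500 bp of a TSS, each with 2 background windows per summit. Rows of the pooled list below the IDR threshold were not excluded from the matched positions. The 13 gene lists were also fixed beforehand. A gene counted when a summit lay within 1000 bp of any of its TSSs, and each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Genes and peaks are not replicates, so these p-values describe the peak set. Of the list symbols, 448 matched the annotation and 4 (*rye*, *Lipin*, *Dl* and *ban*) did not and were left out.

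Named genes followed a rule set before the data were examined. It took *OdsH* and its neighbour *unc-4*; the protein-coding gene with the nearest TSS within 5000 bp of each of the 20 strongest IDR summits supported by all 3 replicates; the ecdysone pathway genes *EcR*, *usp*, *br*, *Eip74EF*, *Eip75B*, *ftz-f1*, *Hr3*, *Hr4* and *Eip93F*; and, per gene list, up to 3 members with the strongest summit within 1000 bp of a TSS. Alternatives covered the overlap rule, windows, peak strength, the build, backgrounds and each replicate left out in turn. For arm shares, the promoter share and motifs, a value without a replicate is the mean of the remaining replicates' own values. Its p-value is the larger of theirs, so such a call is lost whenever a remaining replicate fails alone. Threshold for all adjusted p-values was 0.05.

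All steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The motif, gene list, promoter and arm tests were tested on simulated data, 10 sets of 8700 random summits with nothing planted and 10 with planted signal. Without planted signal the motif test made 0 calls in 150, the gene list test 4 in 130, the promoter test 1 in 10 and the arm test 0 in 60. Random summits do not differ in base composition from their flanks, whereas IDR summits do (31.8 against 43.5% GC). The 0 motif calls therefore do not give the error of the flank comparison in the real data. The 4 gene list calls came after adjustment, so random summits can give some list calls. Planted motifs in 500 summits, planted summits at 15 list genes and planted promoters at 1000 summits were each recovered in 10 of 10 sets.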

Results

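The data describe where an OdsH-GFP fusion protein was found on the genome of whole white prepupae, the stage of puparium formation, which follows a pulse of the steroid hormone ecdysone. OdsH is a paired-class homeodomain protein encoded on the X chromosome beside its paralog *unc-4*. The 3 biological replicates formed a single group. On build dm6 the authors' IDR set held 8700 peaks, which merged into 8282 separate regions covering 2934 kb, or 2.19% of the 6 arms. Peaks had a median width of 416 bp. The authors' signal value ranged from 77.5 to 3230 with a median of 153, and the strongest rows of replicates 1, 2 and 3 reached 858, 1343 and 1145 in their own lists.

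The first question was how well the replicates shared these regions. Of the IDR peaks, 86.9% ± 2.31 (SD, n = 3) were overlapped by a replicate's own 8700 strongest peaks, against 4.44, 4.38 and 4.35% of randomly placed peaks in replicates 1, 2 and 3. All 3 replicates supported 6175 peaks (71.0%), against a mean of 2.78% and a highest value of 3.25% over random placements. The remaining peaks were supported by 2 replicates (1695), 1 replicate (761) or none (69). With replicate lists of doubled length, all 3 supported 94.2%, and 99.6, 99.4 and 97.1% of IDR peaks were overlapped by the full lists of replicates 1, 2 and 3. Ranked into 5 classes of 1740 peaks, 98.9, 96.8, 89.8, 56.3 and 13.1% were supported by all 3 replicates' 8700 strongest, from the strongest class to the weakest, which lies at the rank where both kinds of list were ended. Signal values at shared peaks ranked alike, with Spearman's rho of 0.843 between replicates 1 and 2, 0.818 between 1 and 3 and 0.830 between 2 and 3, computed across 8609, 8411 and 8393 peaks. The IDR set held the strongest rows of a list pooled from these same replicates, which were called against 1 control, so overlap was partly built in and random placement gives only the overlap of unrelated positions. With a reciprocal overlap of 50% the share supported by all 3 was 48.9%.

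The strongest regions lay mainly at promoters. Of the 20 strongest summits, all supported by every replicate, 13 lay within 500 bp of a TSS, and 3 had no protein-coding TSS within 5000 bp. The strongest peak (3L, 19590406 to 19590847, signal value 3230) had its summit 88 bp upstream of *CG14100*, and ranked 1, 2 and 1 in replicates 1, 2 and 3. The next (2L, 480846 to 481353, signal value 3225) lay in an intron, within the bounds of the gene *ush* (2L, 476220 to 540560). The nearest TSS, 1371 bp away with the summit upstream of it, was that of *cbt*, which encodes the zinc finger transcription factor Cabut. *CG11050* followed with a summit 1034 bp downstream of its TSS. *Chro*, encoding the chromatin protein Chromator, and *PNPase*, encoding the mitochondrial polynucleotide phosphorylase, had summits 90 and 85 bp downstream of a TSS with signal values of 2454 and 2427. The kinase gene *Lk6* (2356), *Tcs5* (2339), the UDP-galactose transporter gene *Ugalt* (2322), the mitochondrial ribosomal protein gene *mRpL41* (2307) and the small heat shock gene *Hsp27* (2270) completed the 10 strongest. The others named by the same rule were *CenG1A* (2233), *CG4496* (2208), *larp* (2106), *Art3* (2037), *CG18549* (2003), *CG31145* (1949) and *CG5611* (1907). Their ranks in the 3 replicate lists lay between 7 and 31.

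At its own locus OdsH-GFP had 4 summits within the *OdsH* gene (X, 17791010 to 17814011, plus strand). The strongest of these stood at position 17802908 with a signal value of 674, rank 377 of the IDR set. None lay within 1000 bp of an *OdsH* TSS, and the nearest, in an intron 6110 bp away, was among the weaker peaks (signal value 82.0, rank 8274) and was supported by 1 replicate. The neighbouring paralog *unc-4* (X, 17768569 to 17778708) held no summit, and the closest, supported by all 3 replicates, was intergenic and 7854 bp from its TSS (signal value 295, rank 1799). The flies were transgenic for the fusion. Whether sequence of the transgene adds to the signal at *OdsH* was not tested, so these summits do not establish binding of OdsH to its own gene.

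Summits favoured promoters and introns and were nearly absent from protein-coding sequence. Within 500 bp of a TSS lay 2630 of the 8700 summits (30.2%), against a mean of 13.6% ± 0.368 (SD over placements) of randomly placed summits, a ratio of 2.23 (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). In the replicates' own lists the share was 33.3% ± 1.74 (SD, n = 3). Introns held 46.7% of summits against 39.5% of random positions, and intergenic sequence 20.6% against 27.2%. Coding sequence (CDS) farther than 500 bp from any TSS and outside 5' UTRs held 11 summits, or 0.126%, against 13.6% of random positions with a lowest value of 12.6% over 100 placements. Every replicate showed it, at a mean of 0.157% ± 0.0289 (SD, n = 3). Summits were also fewer in 3' UTRs (0.736% against 4.46%), while 5' UTRs (0.506% against 0.772%) differed less. Peaks near a TSS were stronger: their median signal value was 178, against 143 for the other 6070 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The share near a TSS was 43.0% in the strongest 1740 peaks and 23.4% in the weakest 1740.

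**Figure D1:**
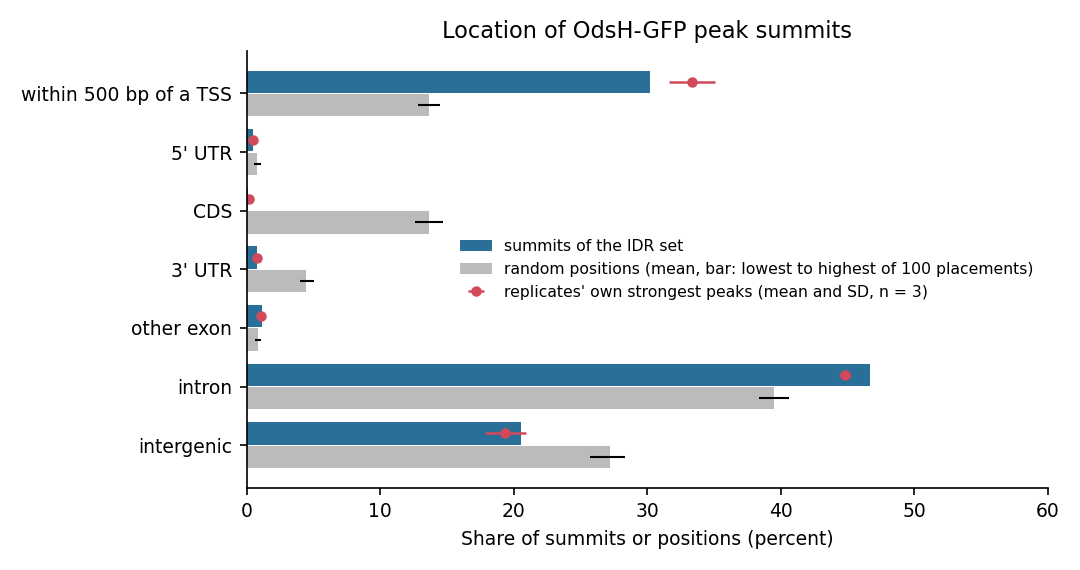
Share of summits (percent) by location, in order of assignment from top to bottom, for the IDR set (blue), random positions (grey, with the lowest and highest of 100 placements) and each replicate's own strongest peaks (red, mean and SD, n = 3). Summits exceed random positions near a TSS (30.2 against 13.6%) and are almost absent from CDS (0.126 against 13.6%).

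Arm 4, the small and largely heterochromatic chromosome, carried 38 peaks, or 0.437% (95% interval 0.309 to 0.599) of the total against 1.01% of the assembled length, a ratio of 0.434 (exact binomial test, adjusted p = 1.1e-08). Arm 2R held 0.856 times its share by length (exact adjusted p = 2.9e-10) and arm 3L 1.10 times (adjusted p = 1.1e-05). The X chromosome, which carries *OdsH*, held 19.2% of peaks against 17.6% of length (ratio 1.09, exact adjusted p = 1.6e-04), and 18.9% ± 1.00 (SD, n = 3) in the replicates' own lists. Arm 2L (1.06, exact adjusted p = 0.0117) and arm 3R (0.944, adjusted p = 0.00364) departed less. Measured against the share of protein-coding genes, the shortfall on arm 4 did not pass the test (ratio 0.761, exact adjusted p = 0.122). The excess on X was lost in the peaks of replicate 1 alone (ratio 1.03, exact adjusted p = 0.172) and in the stronger 4350 peaks (1.04, adjusted p = 0.248). It passed in replicate 2 alone (1.05, exact adjusted p = 0.0406) and in replicate 3 alone (1.14, adjusted p = 7.6e-09). Its losses without replicate 2 (1.09) or replicate 3 (1.04) repeat the failure of replicate 1. The excess on X was also lost on dm3, where arm lengths were approximated by the last pooled peak (1.04, exact adjusted p = 0.181). The differences on 2L and 3R were lost in the peaks of replicates 1 and 2 alone and in the stronger 4350 peaks. Their losses with any replicate left out repeat the failures of replicates 1 and 2. On dm3, with the same approximate lengths, 3R also lost its call (0.976) and 2L turned to 0.974. Against genes 2L turned to 0.976. Peak shares hardly differed between dm6 and dm3 (18.6% in both for 2L, 22.6% in both for 3R, 19.2 and 19.3% for X). The dm3 changes for these arms therefore follow from the arm lengths used.

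Sequence at the summits was rich in A and T. The 101 bp windows at IDR summits had a mean GC content of 31.8%, against 43.5% in windows 500 bp away and 42.2% at random positions, where 100 placements ranged from 41.9 to 42.4%. In the replicates' own lists it was 32.3% ± 0.262 (SD, n = 3). For 85.4% of summits the window had less GC than its own flanks. The dip was present near TSSs (32.9%) and away from them (31.3%), and was deeper in the strongest 1740 peaks (30.1%) than in the weakest 1740 (33.2%).

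**Figure D2:**
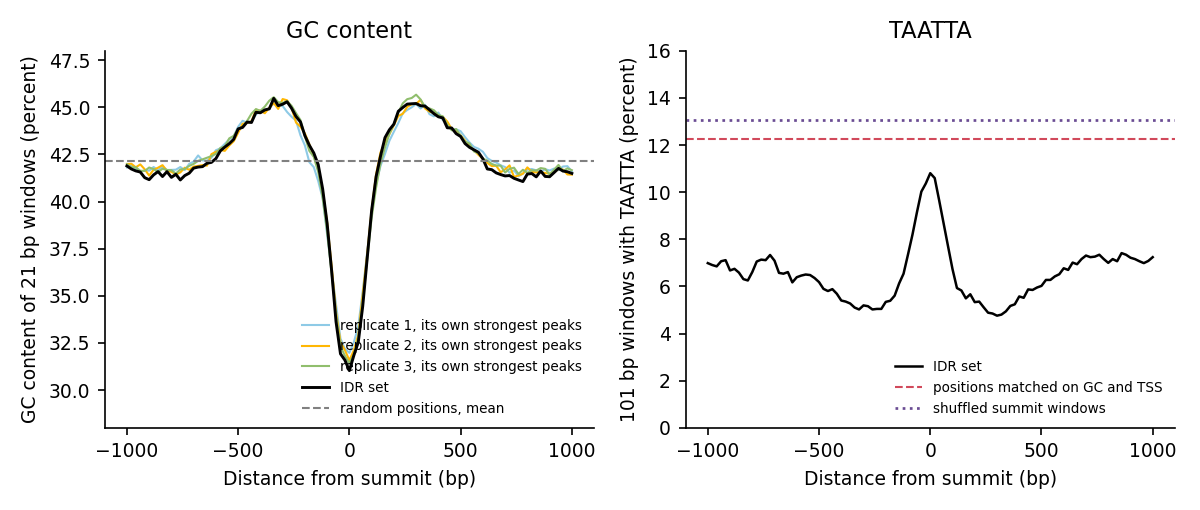
Left, mean GC content (percent) of 21 bp windows by distance from the summit (bp) for the IDR set and each replicate's own strongest peaks, with the mean of random positions dashed; right, share of 101 bp windows with TAATTA by distance, with 2 composition-matched backgrounds as horizontal lines. GC content falls to 31.0% at IDR summits and rises to 45.5% at 340 bp toward lower coordinates and 45.2% at 300 bp toward higher ones. TAATTA reaches 10.8% at the summit, below both backgrounds (12.3 and 13.1%).

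Homeodomain sites were more frequent at summits than in their flanks. TAATTA, the core word bound by many homeodomains, occurred in 10.8% of summit windows against 6.10% of flanking windows (ratio 1.77, Fisher's exact test, adjusted p = 2.9e-38), and the replicates' own lists gave a ratio of 1.70 ± 0.053 (SD, n = 3). The paired-class dimer site TAATNNNATTA occurred in 1.75% against 0.580% (ratio 3.01, exact adjusted p = 1.2e-17) and TAATTG in 11.5% against 9.66% (ratio 1.19, adjusted p = 1.3e-05). None of the 3 words passed as higher once base composition was matched. Against positions of the same GC content and the same nearness to a TSS, the ratio was 0.881 for TAATTA (95% interval 0.820 to 0.947, exact adjusted p = 0.00216), 0.880 for TAATTG (adjusted p = 0.00152) and 0.927 for TAATNNNATTA (95% interval 0.766 to 1.12, adjusted p = 0.769). Against shuffled summit windows TAATTA stood at 0.826 (exact adjusted p = 2.7e-07) and TAATTG at 0.790 (adjusted p = 3.8e-11), while TAATNNNATTA stayed above 1 without passing the test (1.11, 95% interval 0.908 to 1.35, adjusted p = 0.376).

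Motifs of housekeeping promoters behaved differently. TATCGATA, the DNA replication-related element, exceeded its flanks 3.13-fold (exact adjusted p = 5.9e-08) and its matched background 1.61-fold (adjusted p = 0.0190). GGTCACAC, resembling core promoter motif 1 bound by M1BP, exceeded its flanks 2.26-fold (exact adjusted p = 6.2e-04) and its matched background 2.46-fold (adjusted p = 0.00136). Its excess over flanks did not pass with 25 bp to each side (ratio 1.70, exact adjusted p = 0.146) or away from TSSs (ratio 1.83, exact adjusted p = 0.0894). TATCGATA was present in 1.90% of summits near a TSS and 0.181% of the others, a difference larger than counting error (Fisher's exact test, adjusted p = 1.1e-15). Away from TSSs TATCGATA did not exceed its flanks by the test (ratio 1.16, exact adjusted p = 0.838). The matched background was matched on lying within 500 bp of a TSS, not on the distance itself. Summits exceeded random positions more within 200 bp of a TSS (ratio 2.82) than within 500 bp (2.23). The excess of TATCGATA and GGTCACAC over matched positions therefore cannot be told apart from closeness to the TSS. The GATA-like word AGATAAG was higher than its flanks (ratio 1.44, exact adjusted p = 0.00141) but not than the matched background (1.03, adjusted p = 0.940) or shuffled windows (0.983, adjusted p = 0.879). It lost its call over flanks in the stronger 4350 peaks (1.31, exact adjusted p = 0.127) and near TSSs (1.45, adjusted p = 0.104). Lower than their flanks were the GAGA factor-like word GAGAGAG (0.441, exact adjusted p = 3.3e-15), the E-boxes CACGTG (0.438, adjusted p = 4.4e-08) and CAGCTG (0.466, adjusted p = 3.2e-25), the AP-1-like word TGASTCA (0.670, adjusted p = 0.00961) and the control word CCACGTCA (0.1, adjusted p = 0.00618, 1 summit window). None of these was lower than the matched background by the test: CACGTG stood at 0.907 (exact adjusted p = 0.833), CAGCTG at 1.07 (adjusted p = 0.769), TGASTCA at 0.960 (adjusted p = 0.940) and CCACGTCA at 0.167 (adjusted p = 0.183). CCACGTCA also lost its call over flanks with any replicate left out (ratios from 0.380 to 0.458), which repeats failures in single replicates. TGASTCA lost its call without replicate 2 (0.767) or replicate 3 (0.766), both times because replicate 1 alone did not pass (exact adjusted p = 0.259). Both words lost it in summits near TSSs and in those away from them taken separately, CCACGTCA also with 25 bp to each side and in the stronger 4350 peaks, and GAGAGAG near TSSs (0.803, exact adjusted p = 0.263). GAGAGAG was 1.66 times its matched background (exact adjusted p = 0.00152). The Zelda-like CAGGTA (0.846), the nuclear receptor hexamer AGGTCA (0.963), the POU octamer ATTTGCAT (0.879) and the control word ACTGATCG (0.875) did not pass the test over flanks. CAGGTA passed as lower near TSSs (0.662, exact adjusted p = 0.0308) and against shuffled windows (0.759, adjusted p = 0.00531). ATTTGCAT passed as lower with 100 bp to each side (0.804, exact adjusted p = 0.00309) and as higher against shuffled windows (1.48, adjusted p = 6.3e-04). In all, 6 words were higher than the flanks, 5 lower and 4 did not pass, against 3 higher and 2 lower with the matched background.

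**Figure D3:**
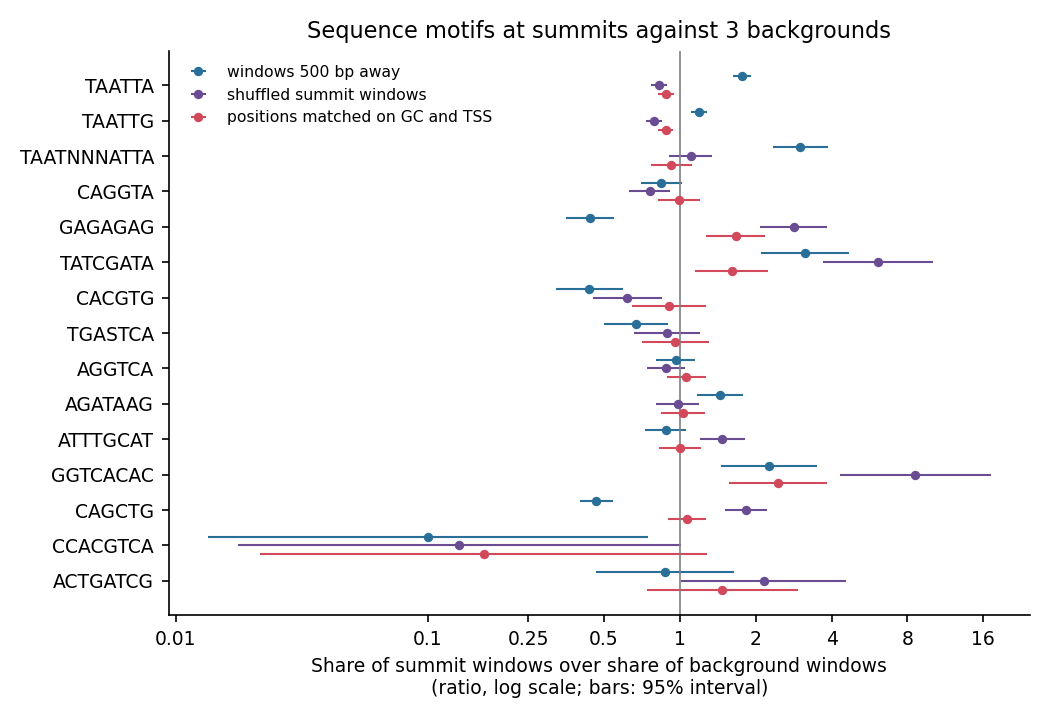
Share of summit windows with each of 15 words over the share in background windows (ratio, log axis), with 95% intervals for counting error, for 3 backgrounds: windows 500 bp away (blue), shuffled summit windows (purple) and positions matched on GC content and nearness to a TSS (red). TAATTA moves from 1.77 to 0.826 and 0.881, while TATCGATA and GGTCACAC stay above 1 against all 3.

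TAATTA was slightly more common in stronger peaks. It occurred in 12.1% of summit windows in each of the 2 strongest classes of 1740 peaks and in 10.1, 9.94 and 9.77% of the following classes. Summits with the word had a median signal value of 166, against 151 without it (two-sided permutation test over 940 and 7760 peaks, p = 0.00102). GC content was also lower in the strongest class (30.1%) than in the weakest (33.2%). Strength was not compared at matched composition, so a link of the word itself with strength cannot be told apart from composition. With windows of 100 bp to each side the difference fell to 6.38 and did not pass the test (permutation p = 0.111).

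Ribosomal protein genes and genes of the ecdysone response had summits more often than other genes. Over all protein-coding genes, 3209 (23%) had a summit within 1000 bp of a TSS. Of the 92 genes for cytosolic ribosomal proteins, 56 did (60.9%, against 22.8% of other genes; Fisher's exact test, adjusted p = 8.9e-14), and 68.1% ± 0.628 (SD, n = 3) by the replicates' own lists. The strongest were *RpS19b* (signal value 890), *RpL7* (661) and *RpL34b* (581), the last 2 with summits close to a TSS and the first with a summit 903 bp away, in an intron of another gene. Of 30 genes of the ecdysone response and metamorphosis, 15 had a summit (50% against 23%, exact adjusted p = 0.00651; 50% ± 3.33 in the replicates, SD, n = 3). They were led by *E23*, encoding an ABC transporter (1171, rank 83), the cell death gene *hid* (712, rank 335) and the nuclear receptor gene *Eip75B* (586, rank 516). A gene with more TSSs offers more room for a summit, and no list was matched on the number of TSSs. Counted by gene body with 1000 bp upstream, against genes of matched length, the ecdysone share was 76.7% against 54.0% (permutation test, adjusted p = 0.0329). That count includes promoters and was not matched on the number of TSSs either. Developmental signalling genes stood at 16 of 33 (48.5% against 23%, exact adjusted p = 0.00651), with the EGF receptor ligand gene *spi* (841), the Notch modifier gene *fng* (782) and the Dpp pathway repressor gene *brk* (566). The replicates' own lists gave 51.5% ± 8.02 (SD, n = 3) for developmental signalling genes. That call was lost when any replicate was left out (exact adjusted p from 0.0723 to 0.192). The set without replicate 1 reached fewer genes than the IDR set (18.7% of those outside the ecdysone list, against 23%). The loss there cannot be put down to the replicate alone.

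Spermatogenesis genes had fewer summits, 2 of 36 (5.56% against 23.1%, exact adjusted p = 0.0296), namely *twe* (132) and *can* (86.5). This call was lost without replicate 2 (exact adjusted p = 0.165) and among peaks supported by all 3 replicates (adjusted p = 0.0622).

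The other lists did not pass the test. Fat body genes stood at 7 of 15 (46.7%, exact adjusted p = 0.124), with the lipase gene *bmm* (372), *Mtp* (350) and *FASN1* (194), and heat shock genes at 8 of 19 (42.1%, adjusted p = 0.124), with *Hsp27* (2270), *Hsp26* (668) and *stv* (642). Fat body genes passed with windows of 500 bp (exact adjusted p = 0.0446) and 2000 bp (adjusted p = 0.0472). Homeobox genes stood at 12 of 77 (15.6%, exact adjusted p = 0.221), with *tin* (523), *H2.0* (246) and *so* (197). Homeobox genes passed as lower in the stronger 4350 peaks (exact adjusted p = 0.0334). Cuticle genes had 3 of 30 (10%, exact adjusted p = 0.221), *Cht7* (576), *kkv* (107) and *Cpr50Ca* (101). Neuronal genes had 4 of 25 (16%, exact adjusted p = 0.701), led by *elav* (972, rank 149), *fru* (259) and *futsch* (104), and glial genes 4 of 14 (28.6%, adjusted p = 0.703), led by *moody* (446), *Gs2* (282) and *loco* (168). Neuronal genes passed as lower when gene bodies were counted against genes of matched length (permutation test, adjusted p = 0.0329). Muscle genes had 6 of 24 (25%, exact adjusted p = 0.809), led by *sls* (437), *Zasp52* (336) and *Tm1* (277). Mitochondrial complex I genes had 10 of 40 (25%, exact adjusted p = 0.807), led by *ND-ASHI* (798), *ND-MWFE* (484) and *ND-75* (348). Of 13 salivary gland glue genes and their regulators, 2 had a summit (15.4%, exact adjusted p = 0.807), the regulators *CrebA* (312) and *fkh* (165).

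**Figure D4:**
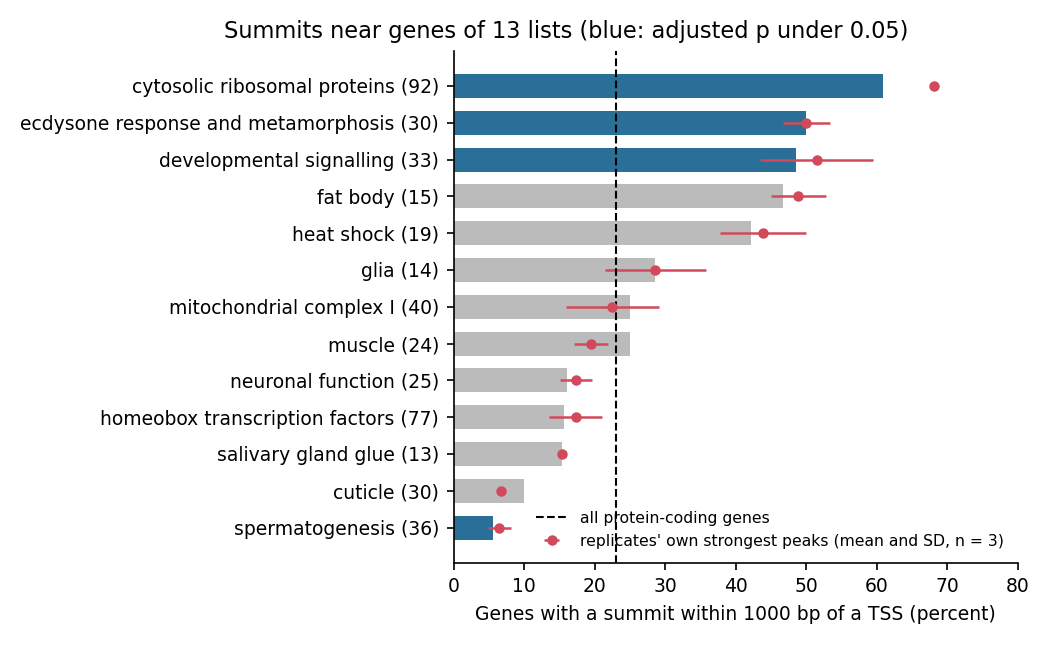
Share of genes (percent) with an IDR summit within 1000 bp of a TSS in 13 gene lists, with the number of genes in parentheses; blue bars passed the test against other genes, the dashed line is the share over all protein-coding genes (23%), and red points give the mean and SD of the replicates' own strongest peaks (n = 3). Ribosomal protein genes (60.9%) and ecdysone response genes (50%) lie above the line, and spermatogenesis genes (5.56%) below it.

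Each core ecdysone gene carried at least 1 summit inside its gene body, but most of these genes are long, and the density of summits differed among them. This density was computed after the counts were seen, and was neither tested nor adjusted for the share of coding sequence. It was 2.85 per 10 kb in *usp* (1 summit in 3.51 kb), 2.70 in *Hr3*, 2.37 in *ftz-f1* and 2.27 in *Hr4*. In *Eip74EF* it was 1.48, in *Eip75B* 1.23 and in *EcR* 1.11. Over protein-coding genes outside the ecdysone list it was 0.577, and *Eip93F* (0.459, 65.4 kb) and *br* (0.223, 89.7 kb) lay lower. *Hr4* held 15 summits, the strongest with a signal value of 1230 (rank 74, X, position 1951903), although none lay within 1000 bp of its TSS. *Eip75B* held 14, with its strongest (829, rank 244) at 3L, position 18011909, and another 33 bp from a TSS. *ftz-f1* held 12, *EcR*, *Eip74EF* and *Hr3* 9 each, *Eip93F* 3, *br* 2 and *usp* 1. The strongest values within these genes were 656 for *Eip74EF*, 423 for *Hr3*, 385 for *EcR*, 347 for *ftz-f1*, 317 for *br*, 294 for *Eip93F* and 230 for *usp*. In *br*, the Broad transcription factor gene, the nearest summit lay 3465 bp from a TSS.

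On build dm3 the authors' set held 8442 peaks, 258 fewer than on dm6. The arms held similar shares in both builds, such as 19.2% on dm6 and 19.3% on dm3 for X and 23% in both for 3L. On dm3 9 peaks lay on scaffolds outside the 6 arms. The dm6 lists had no row outside the arms. As no coordinate was converted, it is unknown whether the sequence of those 9 lies on the dm6 arms.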

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

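The tests of the dimer site's share of windows, of the coding share beyond 500 bp from a TSS and of ribosomal protein genes against classes of other genes were chosen after the results they bear on had been seen. The GC-matched comparisons of location and the comparisons with matched genes were added after the data were examined but before their outcomes were computed.

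Below the authors' IDR threshold, the pooled dm6 list held another 21300 rows, of which 36.5% were overlapped by a row of all 3 replicates' full lists, against a mean of 7.45% and a highest value of 7.90% over 20 random placements. They drew attention because they overlap more often than random placements and lie outside the set used in the comparisons. The pooled list comes from these replicates and 1 control, so the overlap is partly built in and shared background is not excluded. Their summits had a mean GC content of 36.7%, and 17.9% lay within 500 bp of a TSS.

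The dm3 IDR set held 9 peaks on scaffolds outside the 6 arms, 5 on 3LHet, 2 on XHet, 1 on 2RHet and 1 on U. They drew attention because no location, motif, gene list or arm comparison used these scaffolds, which hold heterochromatic or unplaced sequence.

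The AT-rich summits are the first pattern weighed. If base composition of the libraries alone placed the peaks, positions of the same GC content would lie near TSSs as often as summits do. Such positions, drawn outside IDR peaks, did so in 12.8% ± 0.393 (SD over 20 draws) of cases against 30.2%, a ratio of 2.36. This argues against composition alone as what placed the peaks. It cannot tell whether a composition bias within regions selected otherwise made the summits AT-rich. A biological explanation, that the homeodomain selects TAATTA, predicts an excess over positions of equal GC content, and the ratio of 0.881 argues against it for the set as a whole. The dimer site occurred in 1.75% of summit windows, too few to account for the composition of most of them. A longer or degenerate site, open chromatin with AT-rich linkers and a partial composition bias stay open, since no second factor, tag-only control or accessibility track was analysed here.

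The scarcity of summits in coding sequence is the next pattern. Coding sequence is richer in GC, and matching on GC content lowered the random share from 13.6 to 3.36% ± 0.173 (SD over 20 draws), which is still 26.6 times the share of summits, so composition may account for part but not all of it. If summits were merely drawn to promoters, the others would fall in coding sequence as often as random positions do, but beyond 500 bp from a TSS they did so in 0.181 against 15.8% of cases, 0.0115 times as often, which follows from the shares reported for each location and is no separate test. Mappability and the composition of sequence beyond 101 bp were not tested, and no biological explanation was tested.

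The ribosomal protein genes are the last pattern. They had the same medians as other genes for the lowest GC count near a TSS (20 of 101 bases) and for neighbouring genes (1), so genes drawn at matched values, 38 and 37.2 percentage points below the list, differed little from unmatched ones (22.9 and 23.6% with a summit against 22.8%) and tested neither property. Split by class, at most 31.8% of other genes had a summit, in the class with the least GC, and at most 26.7%, in that with 1 neighbour, over classes of at least 92 genes (29.2 and 35.7% in classes of 24 and 28 genes). These shares lie below the list's 60.9% (95% interval 50.1 to 70.9), which argues against either property alone as the cause. High transcription, which can raise recovery of chromatin whatever protein is precipitated, may be a cause and stays open, as no expression data or unrelated GFP precipitation was analysed here.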

How the results depend on the processing

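The coding share with its alternatives, and the alternatives that used peaks supported by all 3 replicates, summits near a TSS, matched genes, GC-matched locations and dm3 peaks on the 6 arms, were added after the data were seen; the others were fixed beforehand. Without 26 values that were no separate test (the strongest pooled rows, matched ribosomal genes and the coding share beyond 500 bp), 386 alternative values for 46 results remained. Of these, 298 kept their direction and side of the threshold, moved less than the replicate spread or, for counts, stayed within 1.5 times the reported count. The 298 also hold changes of direction in which neither value passed. Glial genes, for example, went from 5.57 to -4.74 percentage points against other genes with windows of 500 bp. Another 53 lost their call, 7 gained one, 15 moved farther and 13 reversed where the reported or the alternative value passed. For arms and motifs, losses with a replicate left out repeat failures of single replicates, so they are not independent. Apart from changes of background and of peak number, the cause was not tested. The depth behind each peak is unknown. The promoter share, the signal difference near TSSs and the ribosomal protein and ecdysone calls kept direction and threshold under every alternative among these, and the coding share did so with GC-matched positions, its only one.

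The stronger peaks by signal value number 4350. Support by all 3 replicates was 48.9% with reciprocal overlap of 50%, 63.1% with summits within 100 bp and 94.2% with lists of doubled length. With a replicate left out, support by both remaining replicates was 75.6 to 78.7%, which cannot be lower than support by all 3. Leaving out a replicate gave rho from 0.818 to 0.843.

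Arm ratios lost their call in the stronger peaks for 2L (1.06), 3R (0.967) and X (1.04); in replicate 1 alone for 2L (1.03), 3R (0.980) and X (1.03); in replicate 2 alone for 2L (1.05) and 3R (0.979); and on dm3, with arm lengths taken from the last pooled peak, for 3R (0.976) and X (1.04). Against protein-coding genes 4 lost it (0.761), and 2L reversed to 0.976 there and to 0.974 on dm3. With a replicate left out, as the mean of the other replicates' own lists, 2L ranged from 1.04 to 1.05 and 3R from 0.965 to 0.979. X ranged from 1.04 to 1.10. 2L and 3R lost their call each time and X without replicate 2 or 3. These losses repeat those in single replicates, as the larger of the remaining p-values was taken.

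Against shuffled windows TAATTA (0.826), TAATTG (0.790) and AGATAAG (0.983) fell below 1, and GAGAGAG (2.83), ATTTGCAT (1.48) and CAGCTG (1.83) rose above it. Against GC-matched positions TAATTA (0.881), TAATTG (0.880) and TAATNNNATTA (0.927) fell below 1, and GAGAGAG (1.66) and CAGCTG (1.07) rose above it, leaving 3 words higher and 2 lower. The control word ACTGATCG also rose above 1 without passing, to 2.15 (95% interval 1.01 to 4.58, exact adjusted p = 0.0864) against shuffled windows and 1.47 (adjusted p = 0.583) against GC-matched positions, and AGGTCA to 1.06 (adjusted p = 0.769) against the latter. The change of background is the cause by construction. Lower words numbered 3 away from TSSs (GAGAGAG, CACGTG and CAGCTG) and 3 near them (CAGGTA, CACGTG and CAGCTG). The signal difference with TAATTA was 6.38 with 100 bp to each side.

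Developmental signalling lost its call within 500 bp of a TSS (14.3 percentage points above other genes), with gene bodies (14.3), in the stronger peaks (9.03), among peaks supported by all 3 replicates (12.6) and with a replicate left out (13.9 to 17.6). Spermatogenesis lost it with gene bodies (-10.1), among peaks supported by all 3 replicates (-15.0) and without replicate 2 (-16.8 to -13.1 over replicates left out). Lists below other genes numbered 2 in the stronger peaks, 0 among peaks supported by all 3 replicates, and 0 to 1 with a replicate left out.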

Other observations

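These values were chosen after the data had been examined. Several genes outside the named sets carried many summits. The cell adhesion gene *kirre* (X, 2740384 to 3134532) held 38 over 394 kb, *sbb* (2R, 18278198 to 18357296) 30 over 79.1 kb, *CG43658* (X, 17456169 to 17561180) 26 over 105 kb, and *Snoo* (2L, 7891187 to 7984196) 24 over 93 kb. The transcriptional regulator genes *shn* and *ush* held 21 and 19, at 3.60 and 2.95 summits per 10 kb. Across the 30 ecdysone response genes there were 120 summits in gene bodies, 1.17 per 10 kb, against 0.577 per 10 kb over the other protein-coding genes. This density was not tested. It was not adjusted for gene length, number of TSSs or the share of coding sequence, from which summits were nearly absent.

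The AT-rich summits extended to weak rows of the lists. In the pooled list mean GC content rose from 31.1% in the 5000 strongest rows to 38.5% in rows 25001 to 30000, while the share within 500 bp of a TSS fell from 34.4 to 13.9% and the share in coding sequence rose from 0.1 to 1.84%. In the replicates' own lists the 5000 strongest summits had 31.4% ± 0.137 GC and the 5000 weakest 39.1% ± 1.15 (SD, n = 3). Their shares in coding sequence were 0.107% ± 0.0115 and 3.30% ± 1.42 (SD, n = 3).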
